A study of Mus musculus with 16 samples.

How the data were processed

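The data are gene counts from mRNA sequencing of 16 mouse brain libraries, each made from punches labelled as ventral posterolateral thalamus. Per the labels' protocols, each library pooled 4 punches of 12 gauge taken on both sides from 2 mice, RNA was isolated with TRIzol, and libraries were made with the TruSeq RNA kit, version 2, which does not mark strand. Each library was therefore taken to hold its own animals, so the spread between libraries was read as that between pools. The labels name the sex of all 16 samples as female, while the protocol names male mice.

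The authors deposited whole-number read counts per Ensembl gene, with no normalization. Per the submitters' processing notes, TopHat, DESeq2 and the genome build mm10 were used, with no versions given here. The counter is known only from the 5 summary lines that end each deposited table, which have the form written by HTSeq. The annotation release and the strand setting are not given in the sources used here. Reads that the tables list as without a feature (11.2% to 12.2%), ambiguous (2.2% to 2.3%) or not uniquely aligned (24.1% to 26%) made up 38% to 39.9% of all listed reads, and these lines were left out of library sizes and tests. Gene symbols and positions came from the GENCODE annotation of the same build, which matched 37607 of the 38924 gene IDs; 1317 IDs had no symbol. Reads of overlapping genes, antisense genes and near-identical copies cannot be assigned with certainty from an unstranded kit and unique alignments, so values of such genes are uncertain, whether or not each mention repeats it. Copies were listed for Rplp0, Rpl3 and Rpl34 and otherwise only counted, so other named genes may have them too (42.5% of the genes called in the genotype average did). Also concerned are the antisense gene Gm11413, and genes that overlap another tested gene in position (Ide, Mcmdc2, Zfp125, Cbln1, Lmntd1, Pdzd7, Fam227b, Plin4, Nat8f5, Junb, Grin3b, Nlgn3, Pla2g3, Htra1, Dbp, Tmem267, Bfsp2, Plekhg1, Gpr17 and Slc2a1).

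Samples were placed in 4 groups of 4 libraries from their genotype and treatment labels. Library numbers run through the series and pair no samples, so no paired analysis was possible because no number is shared between groups. Total counts per library ranged from 18.1 M to 78.8 M, with a median of 42.6 M. Replicates of each group differed by more than sampling noise, with chi-square values per degree of freedom between 3.36 and 12.8, so all libraries were kept as separate replicates.

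Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr at a minimum count of 10, which left 18350 genes holding 99.961% of the counts. Libraries were scaled by TMM factors, and a robust quasi-likelihood model with 1 mean per group was fitted to all 16 libraries, so that the groups share 1 estimate of the spread. The common biological coefficient of variation was 6.1%. There were 7 contrasts, namely genotype in naive and in CFA libraries, CFA in each genotype, their interaction, and the average effects of genotype and of CFA. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05. All adjusted p-values for genes are from this edgeR test unless another tool is named. Levels are CPM (counts as a share of the library total, the standard edgeR unit) on TMM-scaled library sizes, given as mean ± SD, and fold changes are the model's, with standard errors (SE) on the log2 scale. Single values were compared by exact two-sided permutation tests, for which 4 libraries against 4 allow no p below 0.0286.

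Before the data were examined, 30 gene lists (pathways, receptor families and markers of cell types and neighbouring regions) were written. They were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over lists within a contrast. Members past the threshold were counted after adjustment over all genes and also adjusted over the list alone. None of the camera calls at the preset correlation, 37 in all, held after adjustment with a correlation estimated from the data, and the adjusted p with that estimate is given beside each list called, except 1 that is not reported here. The other 2 lists gave no set test. The mitochondrially encoded genes had 0 tested members, and the sex-linked genes were used only to check the labels.

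Named genes follow a rule fixed at the same time. In each comparison these are the 10 largest rises and 10 largest falls among called genes with a mean of at least 1 CPM in the higher group and no overlap between the libraries of the 2 groups (not asked of the interaction or the averages), up to 4 members with the lowest p from each list, and Rgs4 and the Grm genes everywhere. Not every gene that meets it is named. Predicted genes without a name are given only where they rank among the first 3. Genes named outside the rule are said to be chosen after their values were seen.

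Alternatives fixed at the same time were RLE size factors, DESeq2 1.42.0, no filter on low counts, a mean of at least 1 CPM, limma-voom with sample quality weights, fits on only the 2 groups compared, each library left out in turn, and 2 other set tests. Added after the data were seen were leaving out naive libraries 7 and 8 of the group labelled KO, thinning all libraries to the total of the shallowest, and adding scores of 3 marker lists to the model. The model was tested on simulated counts with known changes. At changes of 1.25-fold, 1.5-fold and 2-fold it recovered 54.5%, 76.1% and 92.4% of the changed genes for CFA in WT, and 57.6%, 77.6% and 90.9% for CFA in libraries labelled KO. The corresponding shares for the interaction were 44.8%, 67.2% and 75.8%. Between 7 and 13 of the unchanged genes were called in each comparison. The simulation gave every group the same spread for a gene, so it cannot show whether the power was equal between the real groups.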

Results

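The series profiled gene expression in mouse brain punches labelled as ventral posterolateral thalamus, a relay for touch and pain signals to the cortex. RGS4 is a regulator that speeds the switching off of Gi/o and Gq proteins, and the series concerns its part in lasting pain. The 4 groups were wild type (WT) naive, WT after CFA, and the same treatments in libraries labelled RGS4 KO, with 4 libraries each. The labels do not spell out CFA, which in pain research commonly stands for complete Freund's adjuvant, an inflammatory injection. The series text describes a floxed gene and a virus that carries Cre, while the sample labels name only a KO genotype. Mean totals were 42.9 M counts for WT naive, 28.5 M for naive libraries labelled KO, 48.1 M for WT after CFA and 46.2 M for CFA libraries labelled KO. Xist, the transcript of the inactive X, lay between 559 and 747 CPM in every library. The summed level of 4 Y-linked genes was at most 0.172 CPM except in WT naive library 2, where it was 1.3 CPM. For all 16 libraries these levels argue against the male mice named in the protocol and go with the female label.

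Rgs4 was not lower in the libraries labelled KO. Its gene (ENSMUSG00000038530.5) lies on the minus strand of chromosome 1 at 169741477 to 169747642 in mm10. In naive mice Rgs4 was at 80.9 ± 3.66 CPM in WT and 81.3 ± 2.74 CPM in libraries labelled KO (SD, n = 4 each; exact permutation p = 0.886). The 95% interval of the naive fold was 0.93 to 1.09. After CFA it was at 89.3 ± 6.66 CPM in WT and 84.1 ± 5.5 CPM in libraries labelled KO (exact permutation p = 0.229), with a fold interval of 0.871 to 1.01. The 16 libraries ranged from 77.3 to 96.8 CPM. CFA gave a log2 change of 0.14 (SE 0.05, adjusted p = 0.15) in WT and 0.05 (adjusted p = 0.892) in libraries labelled KO. The group is written here as libraries labelled KO because the level of the targeted gene did not set it apart. Counts per gene do not show whether single exons were lost.

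**Figure D1:**
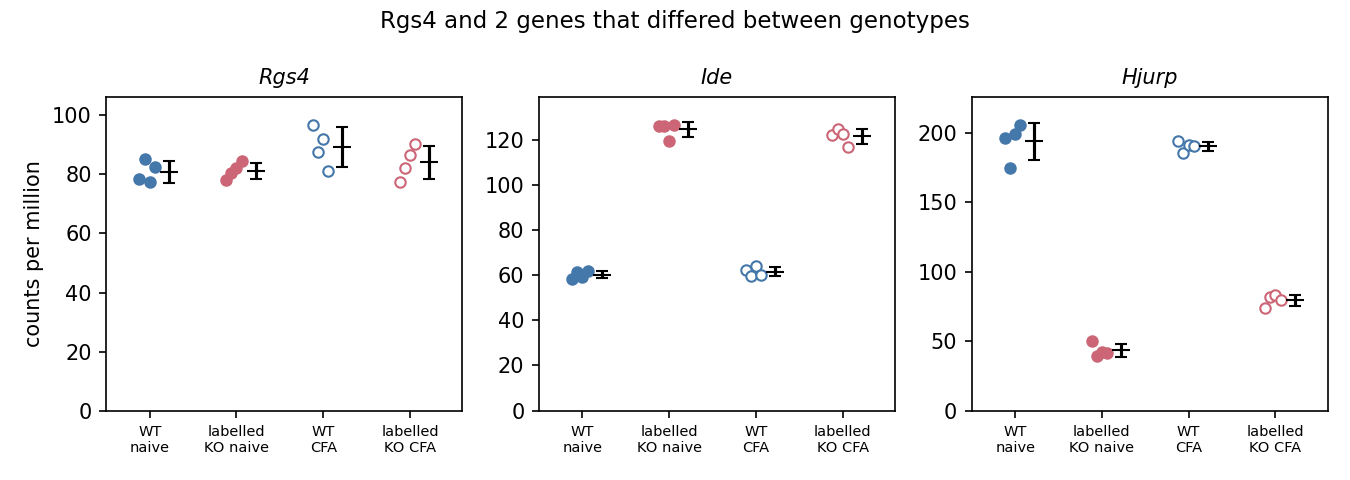
Expression in CPM of Rgs4, Ide and Hjurp in each library, by group. Points are libraries (filled for naive, open for CFA; blue for WT, red for libraries labelled KO) and bars are the mean ± SD of 4 libraries. Rgs4 lay between 77.3 and 96.8 CPM in all 16 libraries, while Ide and Hjurp separated the genotypes.

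The first comparison asked how naive libraries labelled KO differed from naive WT. The protease gene Ide, whose product breaks down insulin, was 2.07-fold higher (60.2 ± 1.62 against 124.5 ± 3.33 CPM, n = 4 each; adjusted p = 2.7e-14). Hjurp, a chaperone that loads the centromere histone, was at 193.8 ± 13.5 CPM in WT and 43.2 ± 4.7 CPM in libraries labelled KO, a fold of 0.225 (adjusted p = 1.16e-12). The meiosis gene Mcmdc2 fell by 4.63 on the log2 scale (SE 0.27). In all, 266 of 18350 genes were called, with 128 higher and 138 lower, and 61 of them differed by more than 2-fold.

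Other genes higher in naive libraries labelled KO were Ccnb1ip1 (18-fold, from 0.0715 CPM), the channel gene Pkd2l1 (3.05-fold), Slc25a41 (2.89-fold), Zfp125 (2.56-fold), Fblim1 (2.19-fold) and Ninj2 (2.19-fold). Lower were Exoc3l2 (fold 0.236), the phospholipase gene Pla2g4e (0.338), the dynein gene Dnah7b (0.371), Dsc3 (0.322), Cryba2 (0.281) and Catsperg2 (0.378). Ribosomal protein genes with near-identical copies moved in opposite directions and are uncertain. Rplp0 fell by 0.78 on the log2 scale while its copies Gm8730 and Gm9625 rose 7.64-fold and 6.23-fold, and Rpl34 rose 1.55-fold while Rpl34-ps1 fell by 4.12. The 3 levels summed to 99.3 ± 4 CPM in WT and 77.4 ± 6.29 CPM in libraries labelled KO (Rplp0, Gm8730 and Gm9625; SD, n = 4 each). Among others, calls were lost without WT naive library 3 for Ninj2 (adjusted p = 0.106) and Rpl34 (0.125), and without naive libraries labelled KO for Cryba2 (0.129) and Catsperg2 (0.146) with library 5 left out, Fblim1 (0.0524) and Dsc3 (0.0562) with library 6, and Pla2g4e (0.0791) and Rpl34-ps1 (0.09) with library 8. The count of 266 was 166 without WT naive library 2, 148 without WT naive library 3, 135 without naive library 6 labelled KO and 169 without naive library 8 labelled KO. DESeq2 called 456 genes, and 92 were called without naive libraries 7 and 8 labelled KO and 68 with 3 marker scores in the model.

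The kappa opioid receptor gene Oprk1 was 1.26-fold higher in naive libraries labelled KO (23.6 ± 1.79 against 29.7 ± 1.23 CPM, n = 4 each; adjusted p = 0.00133), the 1 called member of 33 genes of opioid, monoamine, cannabinoid and muscarinic receptors (2 up adjusted over the list alone). Of 18 thalamic relay markers, Cbln1 (1.38-fold) and Ntng1 (1.13-fold) were higher. Calls of Cbln1 (adjusted p = 0.109) and Ntng1 (adjusted p = 0.117) were lost without naive library 8 labelled KO, among others. None of the 19 other RGS genes, 10 metabotropic glutamate receptor and Homer genes, 42 G protein signalling genes or 20 GABA genes was called in the naive comparison (0 adjusted over the list alone in each). Grm2, a Gi/o-coupled glutamate receptor gene, was at 24.4 ± 0.762 and 23.2 ± 1.84 CPM (adjusted p = 0.652).

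Of 32 genes of inflammation and interferon signalling, 2 were lower and 0 higher in naive libraries labelled KO (1 up and 8 down adjusted over the list alone). The list was called by limma's camera at the preset correlation (adjusted p = 0.00136), and this call was lost with an estimated correlation (adjusted p = 0.241). The 2 genes were Oasl2, an interferon-induced gene (7 ± 1.28 against 3.6 ± 0.875 CPM, n = 4 each), and the complement gene C4b (17.5 ± 3.09 against 10.9 ± 2.17 CPM). The C4b call was lost without naive library 6 labelled KO (adjusted p = 0.0816) among others. No member of 33 immediate early genes was called (6 down adjusted over the list alone), with a median log2 change of -0.25, and a camera adjusted p of 3.51e-05, lost at an adjusted p of 0.783 with an estimated correlation. Of 17 glucocorticoid responsive genes 0 were called (6 down adjusted over the list alone; camera adjusted p = 0.00108, lost at 0.783 with an estimated correlation). Oligodendrocyte markers had a median log2 change of 0.19 with no member called (camera adjusted p = 0.00132, lost at 0.814 with an estimated correlation). Nuclear genes of oxidative phosphorylation had a median of 0.04 with none of 92 called (camera adjusted p = 0.00108, lost at 0.814 with an estimated correlation).

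The second comparison asked the same after CFA. Ide was again higher in libraries labelled KO (1.98-fold; 61.4 ± 1.99 against 121.5 ± 3.28 CPM, n = 4 each), and Hjurp lower (190.1 ± 3.37 against 79.5 ± 4.03 CPM). The bacterial recognition gene Pglyrp1 was 2.82-fold higher (adjusted p = 4.3e-05), the meiotic cohesin gene Rec8 10.8-fold higher, and Pla2g4e fell by 2.32 on the log2 scale (adjusted p = 0.000652). In all, 294 genes were called, with 119 higher and 175 lower. Of the naive calls, 47 higher and 72 lower genes were called in the same direction after CFA, where independent lists of these sizes would share 0.83 and 1.32. These comparisons share no libraries, but they share the spread estimated for each gene from all 16 libraries, so their calls are not fully independent. Across the 18350 genes the 2 genotype effects had a Pearson r of 0.494 and a Spearman rho of 0.116, which describe genes and not independent replicates.

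Further genes higher in CFA libraries labelled KO were Ccnb1ip1 (6.28-fold), Pkd2l1 (2.78-fold), Lmntd1 (2.45-fold), Gstm6 (1.87-fold) and Pdzd7 (1.81-fold), and lower ones were Exoc3l2 (fold 0.179), Fam227b (0.263), Mcmdc2 (0.313), Dnah7b (0.395) and Catspere2 (0.433). Rec8 (adjusted p = 0.0822 without WT CFA library 12), Lmntd1 (0.105 without WT CFA library 10) and Gstm6 (0.0963 without WT CFA library 12) lost their calls with these libraries among others left out. Ccnb1ip1, Rec8 and Pkd2l1 lost theirs in a fit on only the 2 groups compared. The uncertain copies Gm8730 and Gm9625 were 11.5-fold and 7-fold higher and Rplp0 fell by 0.95 on the log2 scale. The count of 294 was 195 without CFA library 16 labelled KO, and DESeq2 called 449 genes. It was 187 with all libraries thinned to the shallowest and 99 with 3 marker scores in the model. Scores of a list of oculomotor and Edinger-Westphal neurons (midbrain motor and peptide neurons), written after the data were seen, lay at 0.96 ± 0.49 in WT and -0.12 ± 0.43 in libraries labelled KO after CFA (SD, n = 4 each; exact permutation p = 0.0286, the smallest possible), a comparison that the choice of the list may favour. None of its 9 tested genes was called (2 down adjusted over the list alone), with a median log2 change of -1.4 (camera adjusted p = 0.000227, lost at 0.258 with an estimated correlation).

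After CFA, Oprk1 was 1.18-fold higher in libraries labelled KO and the adenylyl cyclase gene Adcy2 1.15-fold higher (113.8 ± 4.61 against 130.4 ± 4.79 CPM, n = 4 each), each the 1 called member of its list (33 receptor genes, 42 G protein signalling genes). The irritant-gated channel gene Trpa1 was lower, at 1.59 ± 0.0979 CPM in WT and 0.882 ± 0.185 CPM in libraries labelled KO. Of 16 astrocyte markers 1 was called, the neurotensin receptor gene Ntsr2 (fold 0.802), with 3 down adjusted over the list alone (camera adjusted p = 0.00673, lost at 0.706 with an estimated correlation). The Ntsr2 call was lost in an edgeR fit on only the 2 groups compared (adjusted p = 0.066). The glucocorticoid responsive gene Angptl4 fell by 0.45 on the log2 scale, the 1 called of 17 (2 down adjusted over the list alone; camera adjusted p = 0.0353, lost at 0.991 with an estimated correlation). Its call was lost without CFA library 14 labelled KO (adjusted p = 0.0592) and in 1 other fit. Cbln1 (fold 0.734) and the hypothalamic marker Sim1 (0.611) were lower. The Cbln1 call was lost without CFA library 16 labelled KO (adjusted p = 0.105) among others. Cytosolic ribosomal protein genes had a median log2 change of 0.04 (camera adjusted p = 0.000194, lost at 0.991 with an estimated correlation), with Rpl3 higher and Rplp0 lower, both uncertain because of their copies. Oligodendrocyte markers (median -0.17, none called; camera adjusted p = 0.00673, lost at 0.991 with an estimated correlation) and oxidative phosphorylation genes (median -0.04, of which Cox7b2 fell; camera adjusted p = 0.0236, lost at 0.991 with an estimated correlation) had medians of the opposite sign to the naive comparison.

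Averaged over both treatments, 685 genes differed between the genotypes, with 320 higher and 365 lower in libraries labelled KO, or 442 with all libraries thinned to the shallowest and 795 with 3 marker scores in the model. Ide was 2.02-fold higher, Rec8 10.4-fold, Ccnb1ip1 10.6-fold, Pkd2l1 2.91-fold, Lmntd1 2.42-fold, Pglyrp1 2.2-fold and Bfsp2 2.12-fold higher, while Hjurp (fold 0.306), Exoc3l2 (0.206), Pla2g4e (0.26), Dnah7b (0.383) and Fam227b (0.385) were lower. Inflammatory and interferon genes had 4 members lower and 1 higher of 32 (1 up and 6 down adjusted over the list alone; camera adjusted p = 0.00607, lost at 0.413 with an estimated correlation). Oasl2 (fold 0.564), C4b (0.681), the interferon signal carrier Stat2 (0.908) and the receptor gene Tlr2 (0.715) were lower and the chemokine gene Cxcl12 (1.32) higher. The Tlr2 call was lost without naive library 6 labelled KO (adjusted p = 0.053) and that of Cxcl12 without WT naive library 3 (adjusted p = 0.0721), among others. Of 17 glucocorticoid responsive genes 3 were lower (5 down adjusted over the list alone; camera adjusted p = 0.000423, lost at 0.773 with an estimated correlation), namely Angptl4 (fold 0.755), the metallothionein gene Mt1 (0.9) and Pdk4 (0.767, a call lost without CFA library 13 labelled KO, adjusted p = 0.0973, among others). Astrocyte markers (1 of 16 lower, Ntsr2; 2 down adjusted over the list alone) had a camera adjusted p of 0.0124, lost at 0.549 with an estimated correlation. Immediate early genes had a median of -0.12 with none of 33 called (0 adjusted over the list alone; camera adjusted p = 0.000423, lost at 0.773 with an estimated correlation). Of 78 cytosolic ribosomal protein genes 4 were higher and 2 lower (4 up and 2 down adjusted over the list alone; camera adjusted p = 0.000439, lost at 0.92 with an estimated correlation), with Rpl3, Rps7 and Rpl34 higher and Rplp0 lower. The values of Rpl3, Rpl34 and Rplp0 are uncertain because of copies.

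Genes that differed between genotypes lay close together on the chromosomes. On chromosome 7, 37 of the 99 tested genes that start between 15 and 20 Mb were called in the average, as were 17 of 62 between 120 and 125 Mb of chromosome 2 and 15 of 49 between 145 and 150 Mb of chromosome 6. Of the 671 called genes with a position, 479 had another called gene within 1 Mb, where 10000 random sets of tested genes gave 383 on average and 433 at most (permutation p = 1e-04, the smallest these draws can give). Of the 328 placed genes of the average CFA comparison, 120 had such a neighbour, where random sets gave 121 (permutation p = 0.556). None of the 101 tested genes within 5 Mb of Rgs4 was called by edgeR in the naive, CFA or average genotype comparison.

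**Figure D2:**
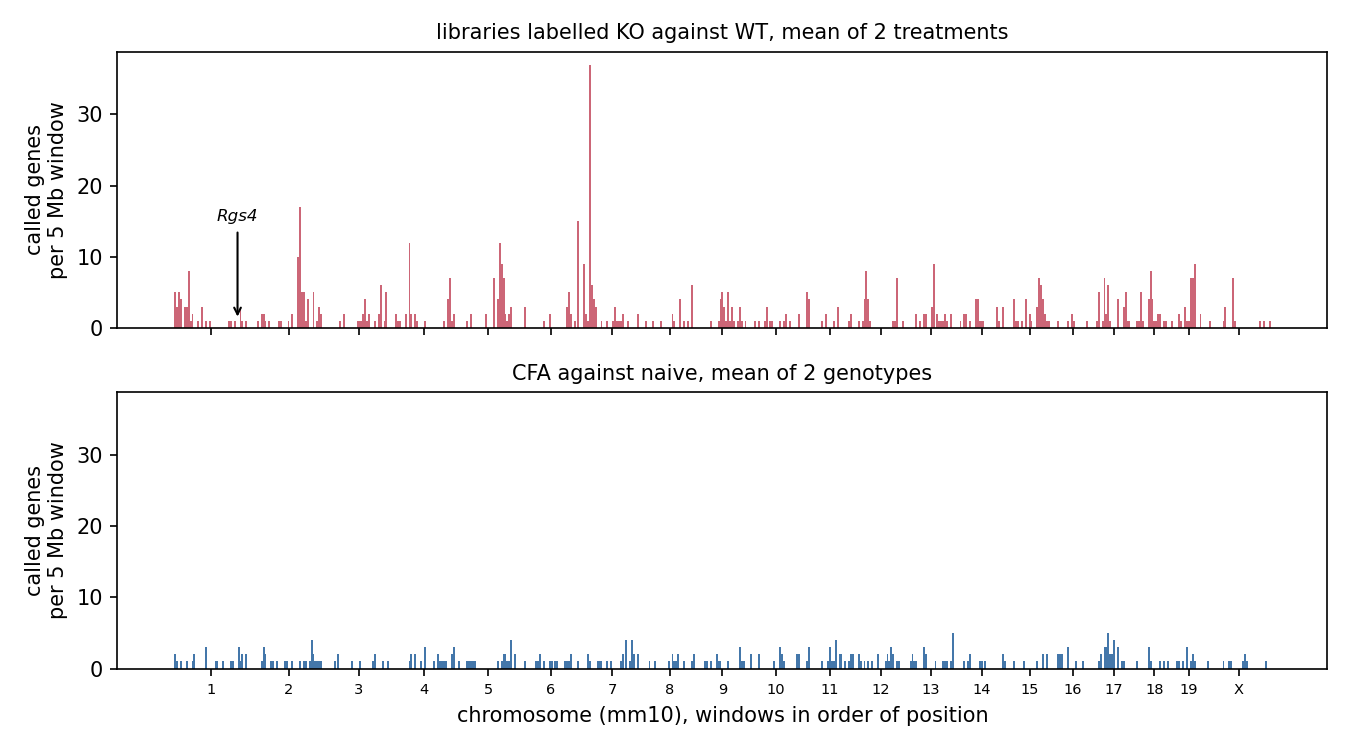
Number of called genes in each 5 Mb window along the chromosomes for the average genotype comparison (top) and the average CFA comparison (bottom). The tallest window, with 37 genes, is at 15 to 20 Mb of chromosome 7 in the genotype comparison, and no CFA window held more than 5. The arrow marks the position of Rgs4.

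The third comparison asked how CFA changed expression in WT. The peptide genes Cartpt (33.2 ± 16.7 to 276.5 ± 33.3 CPM, n = 4 each; adjusted p = 0.024) and Ucn (1.8 ± 1.48 to 17.6 ± 2.61 CPM; adjusted p = 0.0434) had the largest rises along with Foxd2 (13.9-fold, from 0.0726 CPM). The immediate early gene Fos, a marker of recent neuronal activity, fell from 21.1 ± 4.79 to 10.3 ± 1.04 CPM, a call lost in 7 of the fits that left out 1 library. Of 18350 genes, 409 were called, with 261 up and 148 down, and their median change in size was 0.26 on the log2 scale. Both peptide genes are in the oculomotor and Edinger-Westphal list, of which 2 of 9 genes were called (7 up adjusted over the list alone; camera adjusted p = 2.94e-07, lost at 0.103 with an estimated correlation). The list was written after the data were seen and holds genes with large rises, so it is no independent test of them.

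Other genes that rose in WT were the vitamin D receptor gene Vdr (5.4-fold), the peptide gene Calcb (4.87-fold), Postn (4.53-fold), the lipid droplet gene Plin4 (3.33-fold), Chodl (2.72-fold), Spp1 (2.68-fold) and the heat shock gene Hspa1b (2.45-fold). Like Cartpt and Ucn, the genes Vdr, Calcb, Postn, Chodl and Spp1 had means in both groups labelled KO that lay between those of the WT groups. Plin4 and Hspa1b did not. For the genes with this shared form, CFA and a difference in the tissue held by the punches cannot be told apart. Falling genes were Muc6 (fold 0.4), Nat8f5 (0.516), the neurotrophin receptor gene Ngfr (0.585), Dpp4 (0.608) and Rpl29 (0.626). Calls of Vdr, Calcb, Ngfr and Rpl29 held with each library left out in turn. Without WT naive library 2 those of Foxd2 (adjusted p = 0.0934), Ucn (0.125), Cartpt (0.0796), Postn (0.0505), Plin4 (0.0541), Muc6 (0.0571) and Dpp4 (0.083) were lost, and without WT naive library 3 those of Chodl (0.065), Spp1 (0.111) and Hspa1b (0.129). The Nat8f5 call was lost without WT CFA library 12 (adjusted p = 0.0749). The count of 409 was 178 without WT naive library 2, 205 without WT naive library 3, 250, 210 and 225 without WT CFA libraries 10, 11 and 12, and 754 without naive library 8 labelled KO, which enters only the shared spread. DESeq2 called 764 genes, limma-voom 935, edgeR 681 without naive libraries 7 and 8 labelled KO and 246 with all libraries thinned to the shallowest. With 3 marker scores in the edgeR model 0 genes were called, with 1199 at an unadjusted p under 0.05, against 917.5 expected by chance.

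Of 33 immediate early genes 6 fell and 0 rose after CFA in WT (1 up and 13 down adjusted over the list alone; camera adjusted p = 0.000399, lost at 0.796 with an estimated correlation). Besides Fos these included Nr4a3 (fold 0.62), Egr4 (0.636), Junb (0.622) and Egr1 (70.1 ± 10.2 to 44.7 ± 4.86 CPM). Nr4a3 kept its call with each library left out, while Fos (adjusted p = 0.105), Junb (0.096), Egr4 (0.108) and Egr1 (0.11) lost theirs without WT naive library 3, among others. Of 17 glucocorticoid responsive genes 4 rose and 1 fell (7 up and 4 down adjusted over the list alone; camera adjusted p = 0.0125, lost at 0.796 with an estimated correlation). Fkbp5, which dampens the glucocorticoid receptor, rose 1.45-fold, the cell cycle brake Cdkn1a 2-fold and Pla2g3 1.57-fold, and the clock gene Per1 fell by 0.52 on the log2 scale. Fkbp5 (adjusted p = 0.0795) and Cdkn1a (0.0878) lost their calls without WT naive library 2 and Per1 (0.11) without WT naive library 3, among others.

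The channel genes Kcna2 (1.22-fold) and Trpa1 (1.52-fold) rose in WT after CFA. The NMDA receptor genes Grin2c (1.26-fold) and Grin3b (1.86-fold) rose among 18 ionotropic glutamate receptor genes (4 up and 2 down adjusted over the list alone), the receptor genes Htr2a (1.35-fold) and Chrm5 (1.32-fold) among 33 (4 up adjusted over the list alone), and Rgs7bp (1.17-fold) among 19 other RGS genes (1 up and 2 down adjusted over the list alone). The synaptic genes Cplx2 (fold 0.862) and Nlgn3 (0.886) fell, each the 1 called member of its list (30 presynaptic genes, 24 postsynaptic density genes). Cbln1 (1.49-fold) and Ntng1 (1.15-fold) rose among 18 thalamic relay markers (5 up adjusted over the list alone; camera adjusted p = 0.0353, lost at 0.796 with an estimated correlation), as did Cartpt and Sim1 (1.79-fold) among 14 markers of hypothalamus and zona incerta (median -0.10; 3 up and 1 down adjusted over the list alone), Spp1 and Lhx1 (1.29-fold) among 14 of reticular thalamus and other GABA neurons (3 up adjusted over the list alone) and Pde10a (1.12-fold) among 16 of striatum (1 up adjusted over the list alone). Calls of Grin2c, Grin3b, Cbln1, Ntng1, Sim1 and Pde10a held with each library left out. Kcna2 (adjusted p = 0.0736), Htr2a (0.0638) and Cplx2 (0.0667) lost theirs without WT naive library 2, Trpa1 (0.146), Rgs7bp (0.12), Nlgn3 (0.076) and Lhx1 (0.108) without WT naive library 3, and Chrm5 (0.115) without WT CFA library 11. Oligodendrocyte markers had a median of 0.23 with none of 17 called (1 up adjusted over the list alone; camera adjusted p = 0.000661, lost at 0.796 with an estimated correlation), oxidative phosphorylation genes 0.04 with none of 92 called (camera adjusted p = 0.00685, lost at 0.796 with an estimated correlation) and ribosomal protein genes -0.04 with Rpl29 lower (camera adjusted p = 0.00167, lost at 0.796 with an estimated correlation).

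The fourth comparison asked how CFA changed expression in libraries labelled KO. Hjurp rose from 43.2 ± 4.7 to 79.5 ± 4.03 CPM (n = 4 each; adjusted p = 4.89e-06), and Mcmdc2, chosen after its values were seen, from 0.134 ± 0.0958 to 0.921 ± 0.212 CPM. Galnt18 (1.4-fold), the nuclear corepressor gene Hr (36.7 ± 2.73 to 51.6 ± 1.86 CPM), Svil (1.37-fold) and the striatal marker Pde10a (1.17-fold, adjusted p = 0.00142) also rose. Of 18350 genes, 34 were called, with 18 up and 16 down. Of these, 13 up and 8 down were also called in WT, where independent lists would share 0.256 and 0.129. No library is common to both comparisons, but the spread estimated for each gene is, so their calls are not fully independent.

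Also called in libraries labelled KO after CFA were the lipid transporter gene Mfsd2a (1.42-fold), Cmtm3 (1.34-fold), the clock gene Npas2 (1.32-fold), Abcc4 (1.28-fold) and the protease gene Htra1 (1.24-fold) as rises. Tmem267 (fold 0.501), Rpl29 (0.652), Lypd6b (0.715), the sterol synthesis genes Mvd (0.77) and Idi1 (0.808), the clock output gene Dbp (0.814), the transferrin receptor gene Tfrc (0.846) and Ddx10 (0.853) fell. Calls of Hjurp, Mcmdc2, Galnt18, Hr, Svil and Pde10a held with each library left out. Without naive library 6 labelled KO those of Cmtm3 (adjusted p = 0.129), Abcc4 (0.181), Htra1 (0.0716), Rpl29 (0.133), Mvd (0.16) and Tfrc (0.179) were lost, without naive library 8 those of Mfsd2a (0.0658) and Npas2 (0.112), without CFA library 13 those of Tmem267 (0.0559) and Lypd6b (0.0739), and without CFA library 16 those of Idi1 (0.0598), Dbp (0.181) and Ddx10 (0.115). The count of 34 was 16 without naive library 6, 19 without CFA library 13, 16 without CFA library 15 and 16 without CFA library 16, all labelled KO, 17 without naive libraries 7 and 8 labelled KO, 46 with 3 marker scores in the model, and 87 by DESeq2.

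No member of 17 glucocorticoid responsive genes was called in libraries labelled KO after CFA, but 6 were up adjusted over the list alone (median 0.23; camera adjusted p = 1.89e-06, lost at 0.528 with an estimated correlation). Inflammatory and interferon genes had a median of 0.06 with none of 32 called (1 up adjusted over the list alone; camera adjusted p = 0.00183, lost at 0.221 with an estimated correlation). Oligodendrocyte precursor markers had 3 of 9 up adjusted over the list alone and none over all genes (camera adjusted p = 0.014, lost at 0.587 with an estimated correlation). Oligodendrocyte markers (median -0.18; camera adjusted p = 0.014, lost at 0.855 with an estimated correlation) and oxidative phosphorylation genes (median -0.04; camera adjusted p = 0.00148, lost at 0.855 with an estimated correlation) had none called. Immediate early genes had none of 33 called and none adjusted over the list alone.

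The interaction asked which genes responded differently to CFA in the 2 genotypes. The ghrelin receptor gene Ghsr was at 5.29 ± 0.427 and 10.3 ± 0.489 CPM in naive and CFA libraries of WT, and at 7.38 ± 1.41 and 6.74 ± 0.688 CPM in those labelled KO (n = 4 each), a difference of -1.07 on the log2 scale (SE 0.147, adjusted p = 0.00315). The protease gene Prss12 (difference -0.68, adjusted p = 0.00435) had the same form. The peptide gene Cartpt, chosen after its values were seen and not called here, also had it. Cartpt was at 33.2 ± 16.7 and 276.5 ± 33.3 CPM in naive and CFA libraries of WT, and at 110.5 ± 86.6 and 102.8 ± 51.6 CPM in those labelled KO. Hjurp (difference 0.89) and Mcmdc2 (2.95) rose in libraries labelled KO and were level in WT. In all, 12 genes were called, 2 with a positive and 10 with a negative difference.

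Cbln1 (-0.92), Lrrc38 (-1.06), Ndst4 (-0.51), the axon guidance gene Slit3 (-0.49) and the adhesion gene Pcdh9 (-0.43) also differed in their CFA response, as did the predicted genes Gm11413 (-1.41, uncertain as an antisense gene) and, chosen after its values were seen, Gm13339 (-0.41). Calls of Ghsr, Prss12, Hjurp and Mcmdc2 held with each library left out. Without naive library 6 labelled KO those of Lrrc38 (adjusted p = 0.121), Ndst4 (0.121), Slit3 (0.129), Pcdh9 (0.121) and Gm13339 (0.144) were lost, without WT naive library 4 that of Cbln1 (0.076), and without CFA library 16 labelled KO that of Gm11413 (0.0589). The count of 12 was 25 and 27 without naive libraries 5 and 7 labelled KO, 5 without naive library 8 or CFA library 16 labelled KO, and 6 without WT naive library 4, WT CFA library 11, naive library 6 labelled KO, or CFA library 13 or 15 labelled KO. DESeq2 called 86 genes, and 31 were called with no filter on low counts. With 3 marker scores in the edgeR model 0 were called, with 837 at an unadjusted p under 0.05, below the 917.5 expected by chance. Across genes the CFA effects in WT and in libraries labelled KO had a Pearson r of 0.0289 (jackknife SE over libraries 0.101) and a Spearman rho of 0.0741. Of the genes called up and down in WT, 68.6% and 70.3% had the same sign in libraries labelled KO. The Rgs4 difference was -0.10 (adjusted p = 0.693).

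Of the lists, immediate early genes (median difference 0.21, none of 33 called, 2 up and 1 down adjusted over the list alone; camera adjusted p = 0.0109, lost at 0.993 with an estimated correlation), oligodendrocyte markers (-0.35, none of 17; camera adjusted p = 9.53e-07, lost at 0.993 with an estimated correlation) and oxidative phosphorylation genes (-0.07, none of 92; camera adjusted p = 9.53e-07, lost at 0.993 with an estimated correlation) differed at the preset correlation. Markers of reticular thalamus and other GABA neurons did too (-0.23, none of 14, 2 down adjusted over the list alone; camera adjusted p = 0.0262, lost at 0.993 with an estimated correlation).

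**Figure D3:**
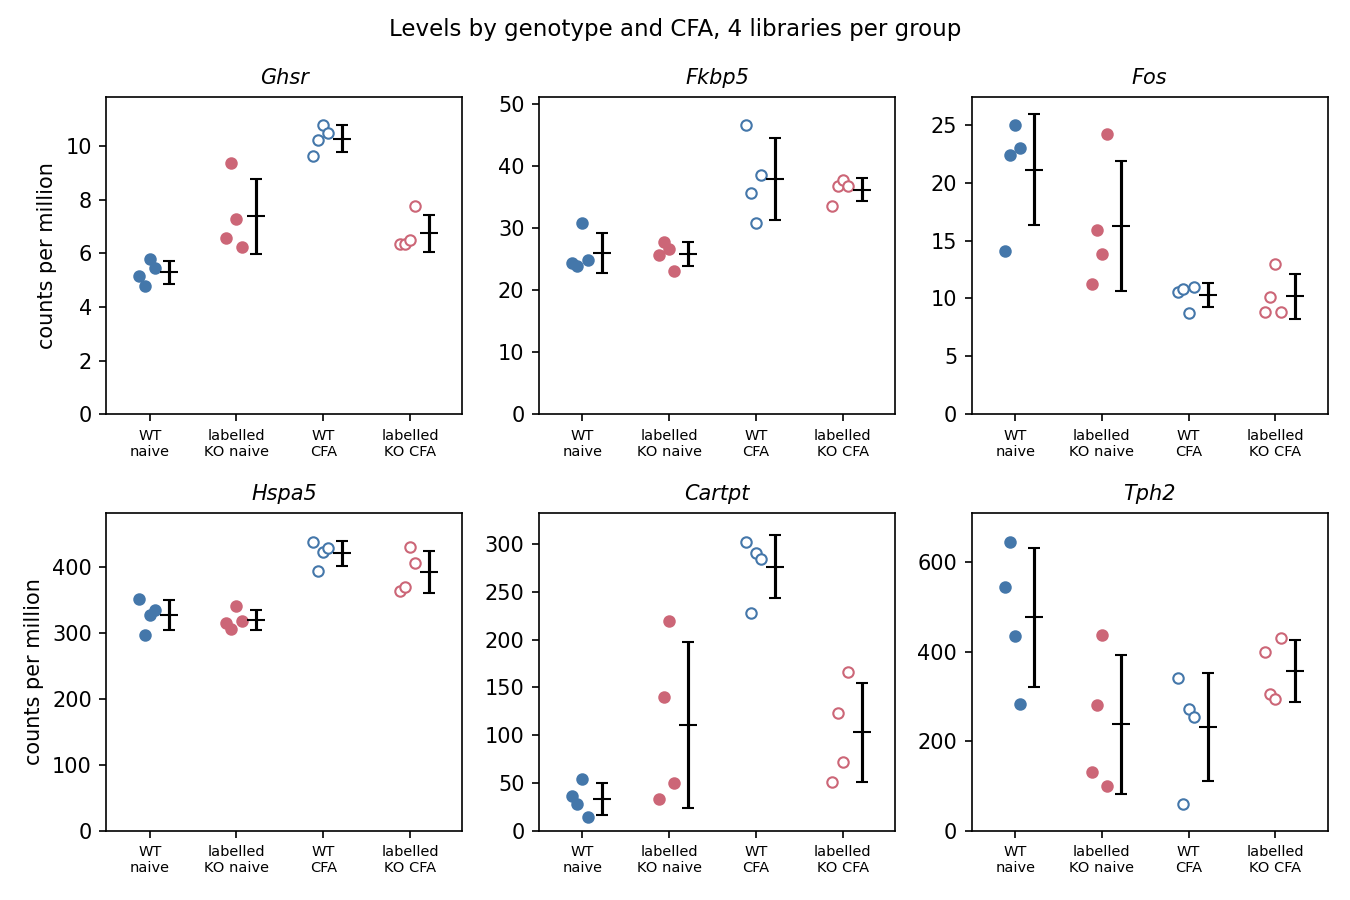
Expression in CPM of 6 genes in each library, by group (filled points naive, open points CFA, blue WT, red libraries labelled KO; bars are the mean ± SD of 4 libraries). Ghsr was higher after CFA in WT and near level in libraries labelled KO. Averaged over genotypes, Fos was lower and Fkbp5 and Hspa5 higher after CFA, though Fos overlapped between naive and CFA libraries labelled KO. Cartpt and Tph2 varied widely between libraries.

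Averaged over both genotypes, CFA changed 332 genes, with 198 up and 134 down. Plin4 rose 3.14-fold, Hspa1b 2.37-fold, Cdkn1a 2.01-fold, the purine enzyme gene Xdh 1.67-fold, the kinase gene Sgk3 1.65-fold, the chaperone gene Sdf2l1 1.58-fold and Hr 1.52-fold, while Fos (fold 0.548), Tmem267 (0.628), Rpl29 (0.639), Dpp4 (0.639) and Nr4a3 (0.668) fell. Of 17 glucocorticoid responsive genes 6 rose and 0 fell (10 up and 2 down adjusted over the list alone; camera adjusted p = 4.29e-05, lost at 0.418 with an estimated correlation), among them Fkbp5 (1.43-fold) and Pla2g3 (1.47-fold). Of 33 immediate early genes 5 fell (7 down adjusted over the list alone; camera adjusted p = 0.00253, lost at 0.778 with an estimated correlation), and besides Fos and Nr4a3 these were Egr1, Junb and Egr4.

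Trpa1 rose (1.42-fold), as did Tnr (1.11-fold) and Gpr17 (1.12-fold) among 9 oligodendrocyte precursor markers (4 up adjusted over the list alone; camera adjusted p = 0.0079, lost at 0.418 with an estimated correlation). Grin2c (1.16-fold) and the astrocyte markers Gjb6 (1.16-fold) and Fgfr3 (1.09-fold) rose, and Nlgn3 (fold 0.886) fell. Of 20 markers of endothelium and mural cells, Slc2a1 (1.13-fold) rose and Itm2a (fold 0.874) fell (median 0.06; 2 up and 1 down adjusted over the list alone). Thalamic relay markers had 2 of 18 up, Prkcd (1.22-fold) and Plekhg1 (1.14-fold), with a camera adjusted p of 0.0343, lost at 0.778 with an estimated correlation (2 up adjusted over the list alone). Inflammatory and interferon genes had a median of 0.09 with none of 32 called (0 adjusted over the list alone; camera adjusted p = 0.0343, lost at 0.418 with an estimated correlation), and of 78 ribosomal protein genes 2 fell (2 down adjusted over the list alone; camera adjusted p = 0.00253, lost at 0.778 with an estimated correlation). Calls were lost with 1 library left out for Egr1 (adjusted p = 0.0751) and Junb (0.101), both without CFA library 13 labelled KO, Egr4 (0.107 without WT naive library 3), Trpa1 (0.0968 without CFA library 14 labelled KO), Prkcd (0.0559 without CFA library 16 labelled KO) and Plekhg1 (0.0617 without CFA library 13 labelled KO), among others. The count of 332 was 204 without WT naive library 2, 206 without naive library 6 labelled KO and 220 without CFA library 16 labelled KO, 567 by DESeq2, 517 by limma-voom and 113 with 3 marker scores in the edgeR model.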

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

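Of the tests below, those chosen only after the result was seen are the count of neighbouring genes, the count of genes that lie alone, all tests of the Rgs4 level and of exchanged libraries, the fits that left out pairs of WT naive libraries, and the settings that thin the libraries, add marker scores or leave out naive libraries 7 and 8 labelled KO.

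Genes that differed between genotypes lay in blocks on the chromosomes. Reads shared with near-identical copies do not account for most of them, since 42.5% of the called genes had a transcript matching another gene at 95% identity over 100 bases, against 37.9% of as many uncalled genes (Fisher's exact p = 0.0948), and a share over 50% had been asked for. Segments of another strain's chromosomes carried by the line labelled KO may be a source. Of 671 placed genes, 479 had a called neighbour within 1 Mb, above all 10000 random sets (433 at most, permutation p = 1e-04, the smallest they can give). CFA calls had 120 against 121 in random sets. The count of neighbours restates the blocks and was chosen after they were seen, so it does not test where they come from. The 192 called genes that lie alone were fewer than in any of the 10000 random sets. The prediction written for an effect of losing RGS4, which asked for as many as in random sets or more, was therefore not met. Nor was the one written for its absence, that no called gene lies alone. The 192 are what remains of the 671 genes after the 479, so their count is no separate test and decides nothing about an effect of losing RGS4. Such an effect on some genes still cannot be told apart from segments, because the same libraries carry both the genotype and any segments. The level of Rgs4 itself was not lower in these libraries. No genotypes of the mice at other loci are given in the sources used here.

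Rgs4 was not lower in the libraries labelled KO. No library was low, the lowest being 0.939 of the median of all 16. This argues against a swap as the source, since no exchange among these 16 could hide a group with low Rgs4. It does not test the labels if the targeted allele keeps its transcript. An exchange of some libraries between the genotypes does not account for the Rgs4 level by another score either. When scored over genes called for genotype in the other treatment, which shares no libraries, 0 of 16 lay on the side of the other genotype (naive -0.309 to -0.195 in WT and 0.212 to 0.275 in libraries labelled KO over 294 genes, CFA -0.316 to -0.21 and 0.251 to 0.267 over 266). Tissue from outside the targeted region might dilute a local loss, and the median gene of the serotonin neuron list lay at percentile 56.3 of tested genes in level with Tph2 at 58.9 CPM or more in every library, which met the bound written for this test. That bound was too loose, because lists of cortex and hippocampus (61.6), striatum (58.9), other GABA neurons (65.4) and thalamic relay neurons (57.1) lay as high. Those of habenula (36.9) and of oculomotor and Edinger-Westphal neurons (36.7) lay lower. This comparison was added after the values were seen, and list medians cannot decide the question. Of single serotonin neuron genes, Tph2 lay at percentile 97.4, Slc6a4 at 96.2 and Fev at 43.9. Serotonin neuron transcripts were thus present in every library, while their share of the tissue and any dilution of an Rgs4 loss stay open. A transcript of the targeted allele could still be counted outside the removed exons, which gene counts cannot show, and the lower 95% limit of the naive fold was 0.93.

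Fewer genes were called after CFA in libraries labelled KO (34) than in WT (409), a ratio of 12, although a difference in counts is not itself a test and the interaction called 12 genes. Sequencing depth does not account for the ratio, which was 8.48 with all libraries thinned to the shallowest. Without naive libraries 7 and 8 labelled KO it was 40.1, which decides nothing alone because fewer libraries in 1 arm also lower its calls. With 2 of the 4 WT naive libraries left out as well, the ratio ranged from 3.35 (104 against 31 genes) to 86 (602 against 7) in 6 fits, so these libraries do not account for all of it. The share of neighbouring tissue in the punches may contribute. With 3 marker scores in the edgeR model WT calls went to 0 and calls in libraries labelled KO to 46, which met the bound written for this test. In WT 1199 genes had an unadjusted p under 0.05, against 917.5 expected by chance, and no other tool was run with the scores. The calls ended mainly through the error, as the median SE went from 0.0546 to 0.108 while the median log2 change went from 0.26 to 0.23 with 98.5% of signs kept, so a condition on effect size was added after the 0 was seen and the tissue share and CFA cannot be told apart in WT. Slopes on the scores taken from libraries labelled KO gave a median share of 0.419 of the WT change and the sign of 68.2% of the called genes (56.7% of uncalled ones), between the bounds written for either outcome.

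Other divisions of the libraries into groups of the same size tested whether chance could give the counts. Only the real split gave as many genes for the naive genotype count (266, highest of the other splits 3, 1 of 35 splits as large). The same was true of the CFA genotype count (294 against 4, 1 of 35) and of CFA in libraries labelled KO (34 against 12, 1 of 35). The last count went down to 16 with 1 library left out. These results met the bound written for each test. As 1 of 35 is the smallest share these splits can give, they make chance unlikely but do not exclude it. For CFA in WT (409 against 8, 1 of 35) the same holds only for the model without marker scores. With 3 scores in the edgeR model its count was 0 (1199 at an unadjusted p under 0.05, against 917.5 expected by chance). For the average genotype effect (685 against 0, 1 of 100), the average CFA effect (332 against 105, 1 of 100) and the interaction (12 against 7, 1 of 100), all 16 libraries were assigned at random. This breaks up the genotype and CFA effects together, so it tests only whether neither label has any effect. It cannot exclude chance for the interaction or for either average alone. The interaction count was also 0 with 3 scores (837 unadjusted) and went down to 5 with 1 library left out.

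The response to CFA differed between genotypes by the interaction test for 12 genes, but for 0 with 3 marker scores in the edgeR model. This loss does not decide between a difference in response and a difference in the tissue held by the punches. The scores of serotonin neurons and of oculomotor and Edinger-Westphal neurons came from lists written after the data were seen. These lists themselves had large median differences, so adding their scores could remove calls either way. Whether the calls ended through a larger error was examined only for CFA in WT. Log2 differences among the 12 genes were -0.51 for Ndst4, -0.68 for Prss12, -1.06 for Lrrc38, -0.92 for Cbln1, 0.89 for Hjurp, 2.95 for Mcmdc2, -1.07 for Ghsr, -0.43 for Pcdh9, -0.49 for Slit3, -0.41 for Gm13339 and -1.41 for the antisense gene Gm11413, which is uncertain. By camera at the preset correlation the CFA response differed for 7 lists, with median differences of 0.21 for immediate early genes, -0.07 for oxidative phosphorylation genes, -0.23 for markers of reticular thalamus and other GABA neurons, -0.35 for oligodendrocyte markers, 1.31 for serotonin neurons, -1.76 for oculomotor and Edinger-Westphal neurons and -0.07 for endoplasmic reticulum chaperones, the last 3 being lists written after the data were seen. These calls were lost with an estimated correlation, at adjusted p-values of 0.993 for each of the first 4, 0.294 for serotonin and for oculomotor and Edinger-Westphal neurons, and 0.356 for the chaperones.

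A single library stood apart from the other 3 of its group in 28 of 572 cases tested (143 measures in 4 groups), where chance gives about 1 in 20. The values that follow are its gap to the nearest other library over the range of the group, all above the 95% limit of Dixon's test for 4 libraries. In WT naive library 2 they were 0.921 for the summed Y genes, 0.981 for Dsc3, 0.841 for Mvd, 0.886 for Slc2a1 and 0.876 for Hmgcs1. In WT naive library 1 they were 0.894 for Dnah7b and 0.957 for Rps7, in library 3 0.856 for Fkbp5, and in library 4 0.838 for Nat8f5 and 0.871 for Ptgds. Among naive libraries labelled KO they were 0.87 for C4b and 0.85 for Hmgcs1 in library 5, 0.892 for Pdk4 in library 6, 0.924 for Ide in library 7, and 0.911 for Angptl4 and 0.842 for Mfsd2a in library 8. Among WT CFA libraries they were 0.863 for Cryba2 in library 10, and 0.914 for Pla2g4e, 0.914 for Lmntd1, 0.902 for Grin2c and 0.99 for Gm13339 in library 11. Among CFA libraries labelled KO they were 1 for the summed Y genes (0.0127 CPM against 0) and 0.831 for Ntng1 in library 13, 0.951 for Rpl34-ps1 and 0.929 for Gpr17 in library 14, 0.839 for Ndst4 and 0.97 for Cxcl12 in library 15, and 0.91 for Ghsr in library 16.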

How the results depend on the processing

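Of the alternatives below, the tests that left out naive libraries 7 and 8 labelled KO, thinned all libraries or added 3 marker scores were chosen after the data were seen. Over 5771 values of named genes under the alternatives, 0 changed sign for a called gene. Of 5427 values of genes called in the reported analysis 4490 kept their call and 937 lost it, of which 631 were among the 3552 with 1 library left out. RLE size factors and a mean of at least 1 CPM kept every such call (222 of 222 and 203 of 203), and DESeq2 215 of 216. With each library left out in turn, counts ranged from 135 (without naive library 6 labelled KO) to 296 (without WT CFA library 9) for genotype in naive libraries, 195 to 407 for genotype after CFA (without CFA library 16 and naive library 8 labelled KO), 178 to 754 for CFA in WT (without WT naive library 2 and naive library 8 labelled KO), 16 to 42 for CFA in libraries labelled KO (without naive library 6 labelled KO and WT naive library 2), 5 to 27 for the interaction (without naive libraries 8 and 7 labelled KO) and 204 to 493 for the average CFA effect (without WT naive library 2 and naive library 8 labelled KO). DESeq2 called 456, 449, 764, 87, 86 and 567 genes in the same order, limma-voom 935 for CFA in WT and 517 for its average, and no filter on low counts gave 31 for the interaction. Without naive libraries 7 and 8 labelled KO the counts were 92 for genotype in naive libraries, 681 for CFA in WT and 17 for CFA in libraries labelled KO. Thinning, which lowers the counts behind each gene, gave 187 for genotype after CFA, 246 for CFA in WT and 442 for the average genotype effect. With 3 marker scores in the edgeR model the counts were 68 for genotype in naive libraries, 99 after CFA, 0 for CFA in WT (1199 unadjusted), 0 for the interaction (837 unadjusted), 113 for the average CFA effect and, above those reported, 46 for CFA in libraries labelled KO and 795 for the average genotype effect. By chance 917.5 genes are expected at an unadjusted p under 0.05. Of 37 set tests called by camera, 0 were called with an estimated correlation, and fry called 3. The cause was not tested, except that leaving out libraries and thinning reduce the data by construction.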

Other observations

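The lists in this part were written after the data were seen, and so were their tests. Genes of sterol synthesis and uptake fell after CFA averaged over genotype, with 11 of 25 called (21 down adjusted over the list alone; camera adjusted p = 8.26e-20, and 0.0326 with an estimated correlation). They included the mevalonate pathway genes Mvd (log2 change -0.41), Idi1 (-0.24) and Hmgcs1 (-0.19), all chosen after their values were seen. The list had 2 called members in WT (14 down adjusted over the list alone; camera adjusted p = 0.103 with an estimated correlation) and 2 in libraries labelled KO (11 down adjusted over the list alone; camera adjusted p = 0.0556 with an estimated correlation). Chaperones of the endoplasmic reticulum, which fold secreted proteins, rose, with 11 of 17 called on average (14 up adjusted over the list alone; camera adjusted p = 1.64e-18, and 0.0131 with an estimated correlation). In WT 11 were called (14 up adjusted over the list alone; camera adjusted p = 0.0227 with an estimated correlation) and in libraries labelled KO 1 (10 up adjusted over the list alone; camera adjusted p = 0.0556 with an estimated correlation). Hspa5 went from 327.4 ± 22.7 to 420.7 ± 19.1 CPM in WT and from 319.6 ± 14.9 to 392.6 ± 31.6 CPM in libraries labelled KO (n = 4 each; the second call was lost in 9 of the fits that left out 1 library, with an adjusted p of 0.181 without naive library 6 labelled KO), with average log2 changes of 0.33 for Hspa5, 0.66 for Sdf2l1 and 0.26 for Pdia4. Among 17 clock genes Npas2 rose (log2 change 0.48) and Dbp fell by 0.30 on the log2 scale, with 2 up and 1 down called (3 up and 8 down adjusted over the list alone; camera adjusted p = 0.0168, lost at 0.155 with an estimated correlation). The times of day at which tissue was taken are not given in the sources used here.

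The punches held transcripts of several neuron types. Tph2, the enzyme that starts serotonin synthesis, averaged 326 CPM over the 16 libraries (58.9 to 646), and the serotonin transporter gene Slc6a4 252 CPM (42.1 to 514). The GABA synthesis gene Gad2 averaged 545 CPM, the vesicular glutamate transporter gene Slc17a6 470 CPM and the thalamic marker Tcf7l2 138 CPM. Other thalamic relay markers were lower, with Prkcd at 14, Ramp3 at 2.66 and Tnnt1 at 1.01 CPM. The peptide genes Cartpt (14.3 to 303 CPM) and Ucn (0.245 to 19.9 CPM) varied widely, as did the choline transporter gene Slc5a7 (mean 20.7 CPM). Tph2 in WT was at 477.3 ± 156 CPM in naive and 231.3 ± 121 CPM in CFA libraries (n = 4 each; edgeR adjusted p = 0.333). Scores of the serotonin list gave an exact permutation p of 0.0571 for genotype in naive libraries, 0.457 after CFA, 0.114 for CFA in WT and 0.229 in libraries labelled KO, where 0.0286 is the smallest possible. The list's median log2 changes in the same order were -0.85 (camera adjusted p = 2.59e-07, lost at 0.41 with an estimated correlation), 0.40 (0.00388, lost at 0.496), -0.82 (1.79e-06, lost at 0.236) and 0.47 (8.76e-05, lost at 0.346), with none of 15 genes called by edgeR. Whether the share of serotonin neurons differed between the groups is left open.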
